A study of Drosophila melanogaster with 2 samples.

How the data were processed

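Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of a transgenic strain that expresses nerfin-2 fused to eGFP, aged 8 to 24 h per the labels. Per the labels, an anti-GFP antibody was used and the chromatin was sheared by sonication. The series holds 2 samples, labelled biological replicates 1 and 2 of 1 group, and lists of peaks rather than reads. A control experiment is named in the labels but was not analysed here, so no value is compared with an input or mock immunoprecipitation. Read numbers are not in the lists, so the sequencing depth of each replicate is unknown from them. The aligner and the peak caller are not given in the sources used here.

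The authors placed the peaks on genome build dm6, per the labels and the text deposited with the samples. They deposited a thresholded and a relaxed ranked list for each replicate. From the reads of both replicates together they deposited a conservative thresholded list, a second thresholded list and a ranked list behind each. The ranking uses the irreproducible discovery rate (IDR), which asks how well a peak's rank holds between 2 sets of calls. In the deposited lists, the score is a whole number that rises as the IDR falls. The deposited signal is the peak caller's signal value. The authors did not state how it relates to a control, and it was not rescaled between lists here. The relaxed ranked lists also hold a deposited −log10 (IDR) value. Each thresholded peak was found in a ranked list, and the highest IDR was 0.00999 in the conservative list. Ranked calls with a score as high as the lowest thresholded score but missing from the thresholded list numbered 89 for the conservative list, 116 for the second list, 84 for replicate 1 and 70 for replicate 2. The reason is not given in the sources used here. The 16 columns per sample in the ranked lists across replicates were not used here.

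Peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y were analysed. Peak ends were checked against the lengths of the reference sequences, and no peak ran past an arm's end. Transcription start sites (TSSs), exons and gene types came from the Ensembl 115 annotation, and sequence came from the Release 6 assembly. Overlap meant at least 1 bp in common. Each replicate's shared percentage was compared with 1000 circular shifts of replicate 2's peaks within each chromosome. Spearman's rho was computed across peaks, which are not independent replicates, and has no p. A summit was placed in the first class that applied among promoter (within 500 bp of a protein-coding TSS), 5′ UTR, coding exon, 3′ UTR, intron and intergenic. Location and chromosome were compared by two-sided Fisher's exact tests with summits of the relaxed ranked list outside every conservative peak.

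A protein-coding gene was bound when a conservative summit lay within 500 bp of any of its TSSs. The background was the 11817 genes with a relaxed summit within 500 bp of a TSS, since those could have been called. The 21 gene lists were the neuroblast and ganglion mother cell, neuroblast temporal series, pan-neuronal and synaptic, axon guidance and neural adhesion, glia, neuropeptide, peripheral sense organ, Notch, Hippo, Hox, segmentation, mesoderm and muscle, endoderm and gut, epidermis and trachea, ribosomal protein, proteasome, heat shock, replication and cell cycle, Polycomb and Trithorax, chemosensory receptor, and chorion and yolk lists. Of 467 written symbols, 18 were not matched and 9 were matched through a synonym. Of the 21 lists, 5 (ribosomal protein, proteasome, heat shock, chemosensory receptor, and chorion and yolk) were defined by symbol patterns rather than by written symbols. Windows of 50 bp on each side of a summit were searched on both strands for 20 fixed motifs and for the 2080 distinct 6-mers. They were compared with windows of the same size centred 500 bp to each side, and each motif's reversed string was counted as a control. All Fisher tests were two-sided, with a threshold of 0.05. Those printed with an adjusted p had Benjamini-Hochberg adjustment within each family. Those printed with a plain p, in the nerfin-2 region and the closing observations, were not adjusted. Confidence intervals are at 95%, from Wilson's method for shares and from the log odds ratio for odds ratios, with 0.5 added where a cell was empty. They cover counting error over peaks or genes only. The lists, motifs, tests and the rule for naming genes were chosen before the data were examined.

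Genes were named by rule. They were nerfin-2 and nerfin-1, the nearest gene of the 15 conservative promoter peaks with the highest signal, and that of the 5 such peaks away from promoters. Up to 4 bound members with the highest signal were named from each list past the threshold and up to 2 from each other list. Other genes named are marked as outside the rule, given as examples or said to be chosen after their values were seen. The exceptions are the non-coding neighbours of peaks away from promoters and the genes at the edges of the nerfin-2 region.

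Alternatives were the second list, the lists of single replicates, the 500 peaks with the highest signal, promoter windows of 250 and 1000 bp, the nearest TSS at any distance, all protein-coding genes as background, and logistic regression on gene length and TSS number. Others were 1000 random placements, motif windows of 100 bp, location-matched relaxed summits as background (5000 requested and 5001 drawn), promoter or other peaks alone, reciprocal overlap of 50%, and summits within 100 bp. Alternatives added after the data were seen left out the peaks around nerfin-2, kept the strongest of overlapping peaks, used all conservative peaks or the 500 strongest pairs for the correlation, and required an IDR above 0.05 in the other replicate for peaks of 1 replicate. The alternatives for the nerfin-2 region were also added then. Leaving out a replicate meant using the other replicate's own thresholded list, so the calling procedure changed with the replicate.

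The tests were tried on simulated data. The ribosomal protein list, with 84 genes, was given a true odds ratio of 3. It was called in 94% of 100 simulations, with a median estimate of 2.93, and 0.35% of unchanged lists were called. Power for the other lists, most of them smaller, was not simulated. Genes were drawn independently, so genes that share a summit were not modelled. A DRE planted in 10% of 2793 windows gave an excess of 9.76 percentage points, with 0 other motifs called. Of the 6-mers of the planted site, 2 of 2 were called, as were 3 6-mers that share under 5 bases with it. Placing 60% of simulated peaks on the other replicate's peaks gave an overlap of 60.4%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 1.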

Results

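Binding of an eGFP-tagged nerfin-2 protein was mapped in whole Drosophila melanogaster embryos aged 8 to 24 h by ChIP-seq with an anti-GFP antibody. The gene nerfin-2 encodes a zinc finger protein related to nerfin-1, a regulator of early neurons and the fly counterpart of vertebrate INSM1. The series consists of 1 group with 2 biological replicates, and the data are peak lists on genome build dm6. The conservative list across both replicates held 2796 peaks, of which 2793 lay on the main chromosome arms. Their signal, the peak caller's value, had a median of 121 and ranged from 2.08 to 1243. Replicate 1 alone gave 2555 thresholded peaks with a median signal of 76.1, and replicate 2 gave 1758 with a median of 73.8. A second list across replicates held 3369 peaks. Read depth is unknown from the lists, and intervals cover counting error over peaks or genes only.

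The replicates were compared to ask whether both embryo collections gave the same sites. The strongest conservative peak, at the promoter of the ubiquitin ligase gene Ube3a, had a signal of 696 in replicate 1 and 532 in replicate 2. The peak at MESK2 had 534 and 530, and that at the proteasome gene Rpn6 had 528 and 401. Of the 15 named promoter peaks with the highest signal, 14 had the higher signal in replicate 1, and Mic26-27 was the exception with 264 and 304. On the main arms, 1523 of the 2554 peaks of replicate 1 (59.6%, 95% Wilson interval 57.7 to 61.5) overlapped a peak of replicate 2. In the other direction, 1477 of 1737 (85.0%, 83.3 to 86.6) overlapped. Shifting the peaks along each chromosome gave a mean overlap of 0.838% and a maximum of 1.61% for replicate 1, with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Across 1184 pairs of overlapping peaks, the signals had a Spearman rho of 0.804. Peaks are not independent replicates, and the lists hold only calls that passed a threshold, so no p is given. Conservative peaks overlapped 80.9% of the peaks of replicate 1, 93.3% of those of replicate 2 and 77.1% of those of the second list.

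**Figure D1:**
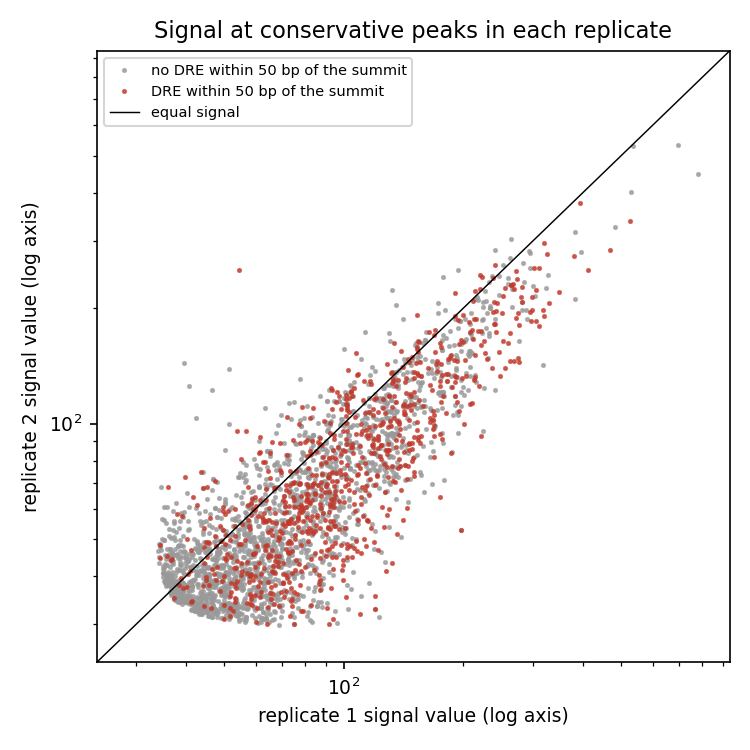
Signal of each conservative peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with a line at equal signal, where a point is a peak with a relaxed call in both replicates, red with a DRE motif (WATCGATW) within 50 bp of the summit and grey without. The 2644 peaks had a Spearman rho of 0.778 and a median ratio of replicate 1 to replicate 2 of 1.26.

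Sites called in a single replicate were compared with shared sites to ask what kind of site differs between the collections. Promoters made up 69.2% of the 1031 peaks found in replicate 1 alone, against 84.8% of its 1523 shared peaks (odds ratio 0.403, 0.332 to 0.488, adjusted p 2.68e-20). For replicate 2, promoters made up 61.2% of the 260 peaks found there alone and 85.3% of the 1477 shared peaks (odds ratio 0.271, 0.203 to 0.362, adjusted p 1.05e-17). Peaks of a single replicate were weaker, with a median signal of 57.6 against 102 in replicate 1 and 49.9 against 81.8 in replicate 2. Promoter shares were not compared at matched signal, so a difference in kind of site cannot be told apart from one in signal.

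Most binding sites lay at the starts of protein-coding genes. Promoters held 2151 of the 2793 conservative summits (77.0%, 75.4 to 78.5) and 12.5% of the 146161 relaxed summits outside conservative peaks, an odds ratio of 23.4 (21.4 to 25.5). Promoter summits lay a median of 53 bp from the nearest TSS. Introns held 302 summits, 10.8% against 37.3% of the relaxed summits (odds ratio 0.204, adjusted p 3.43e-217). Intergenic sequence held 224 (odds ratio 0.256), coding exons 82 (0.117), 3′ UTRs 28 (0.303) and 5′ UTRs 6 (0.218). The adjusted p of these 4 classes was at most 1.97e-06. Against 1000 random placements, promoters held a mean of 11.5% and at most 13.96% of peaks, with a permutation p of 0.001, the smallest that they can give.

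The chromosome arms differed in how many peaks they held, by small factors except on Y. Arm 2R held 619 conservative peaks, with an odds ratio of 1.23 (1.13 to 1.35) against the relaxed list and an adjusted p of 6.04e-05, and 2L had an odds ratio of 1.11 (adjusted p 0.0462). Arms 3R (0.871, adjusted p 0.00557) and 3L (0.883, adjusted p 0.0206) held fewer peaks. Chromosome Y held 1 peak (0.0744, adjusted p 0.00021), and X, with an odds ratio of 0.978, did not pass the threshold (adjusted p 0.675). Chromosome 4, with 19 peaks, had an odds ratio of 1.70 (adjusted p 0.0462), which fell to 0.990 without replicate 1 (adjusted p 1, range over alternatives 0.000533 to 1). Of the arms, 6 passed the threshold, 2 did so without replicate 1 and 4 without replicate 2. Without replicate 1, the odds ratio was 1.06 for 2L, 1.14 for 2R, 0.920 for 3R and 1.14 for X, none past the threshold. Without replicate 2, 2L had 1.02 and 3L 0.936, neither past it, chromosome 4 had 2.35 and Y 0.0407. With the 500 strongest peaks, 3R had 1.03 and Y, at 0.210, did not pass.

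The highest signals at promoters belonged to genes with varied roles. Ube3a (FBgn0061469) had the strongest peak of all, at 3L 11210472 to 11210851, with a signal of 1243 and a summit 62 bp from the TSS. It was followed by MESK2 at 1068, Rpn6 at 925, the integrin-linked gene Fit2 at 872 and milt, which encodes an adaptor for mitochondrial transport, at 819. Next came Capr with 775, the adducin gene hts with 773 and the ribosomal protein gene RpL32 with 721. The RNA helicase gene kz had 683, the cadherin gene kug 667, CkIIalpha-i1 629 and EndoGI 621. CtsF had 599, CG8617 598 and the mitochondrial inner membrane gene Mic26-27 584. All 15 peaks had a relaxed call in both replicates.

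Away from promoters, a single site stood out. A peak in an intron of org-1 (FBgn0021767), a T-box gene, at X 8452204 to 8452539 had a signal of 1228, the rank 2 of all conservative peaks, with 781 in replicate 1 and 447 in replicate 2. The next such peaks were weaker. The peak nearest CG1142 had 452 and lay 118 bp from the start of the small nuclear RNA gene snRNA:7SKa. Those nearest stnB, Adf1 and ArgRS had 436, 380 and 376. The stnB peak lay 20 bp from the start of the non-coding RNA gene asRNA:CR45009. The ArgRS peak lay 333 bp from that of an INE-1 transposable element.

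Gene lists were compared to ask which functions the bound genes serve. Genes for ribosomal proteins and the proteasome were bound more often than other genes, and receptor genes for smell and taste were almost never bound. In all, 2709 of 11817 genes that could have been called (22.9%) had a conservative summit at a promoter. A summit near the TSSs of several genes counted for each of them, so genes that share a summit were not independent in the tests. Of 84 ribosomal protein genes, 36 were bound (odds ratio 2.54, 1.65 to 3.92, adjusted p 0.000679), the strongest being RpL32 with 721, RpS2 with 366, RpS7 with 362 and RpS30 with 299. Of 42 proteasome genes, 18 were bound (2.53, 1.37 to 4.67, adjusted p 0.0335), led by Rpn6, Rpn10 with 262, Prosbeta2 with 262 and Prosbeta1 with 201. The symbol patterns of both lists also took in related gene copies, such as RpS5b, RpS19b, Prosalpha3T, Prosbeta2R1 and Rpn12R, and none of those named here was bound. The proteasome difference did not pass in 5 of 11 alternatives. Without replicate 1 its odds ratio was 2.35 and the adjusted p 0.0930, within a range of 0.00503 to 1 over alternatives. With the 500 strongest peaks alone, the odds ratio of the ribosomal list was 1.79 and its adjusted p 1, in a range of 3.38e-05 to 1.

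Among 137 chemosensory receptor genes, 2 were bound, Ir31a with a signal of 103 and Ir76a with 86.8 (odds ratio 0.0491, 0.0121 to 0.199, adjusted p 7.55e-12). This difference passed the threshold in all 11 alternatives run, with an odds ratio of 0.0187 without replicate 1 and 0.0270 without replicate 2. Of 20 peripheral sense organ genes, 0 were bound (odds ratio 0.0818, 0.00495 to 1.35, adjusted p 0.0384). Without replicate 1 that odds ratio was 0.127 with an adjusted p of 0.213, and without replicate 2 it was 0.196 with 0.196, within a range of 0.0229 to 1 over 10 alternatives.

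The other 6 neural lists did not pass the threshold, though 2 of them did under alternatives. Of the 29 neuroblast and ganglion mother cell genes, 2 were bound, the growth regulator brat with a signal of 273 and opa with 94.2 (odds ratio 0.248, adjusted p 0.103). With a promoter window of 250 bp that odds ratio was 0.126 (adjusted p 0.0377, range over alternatives 0.0377 to 1), and without replicate 2 it was 0.595 (adjusted p 0.691). The neuroblast temporal series had 1 of 16, chinmo with 102 (0.224, adjusted p 0.213), and 0.532 without replicate 2. The pan-neuronal and synaptic list had 4 of 38 (0.395, adjusted p 0.154), among them the adhesion gene Nrg with 473 and the potassium channel gene eag with 186. It passed with 0.190 at 250 bp (adjusted p 0.0377) and with 0.244 in logistic regression on gene length and TSS number (adjusted p 0.0410), in a range of 0.0377 to 1. Axon guidance and neural adhesion had 12 of 39 (1.5, adjusted p 0.354), with the netrin receptor gene fra at 322 and Ptp10D at 216. Glia had 5 of 21 (1.05, adjusted p 1), with Cont at 317 and loco at 113, and its odds ratio turned to 0.549 without replicate 1 and 0.876 without replicate 2. The neuropeptide list had 1 of 26, the amidating enzyme gene Phm with 218 (0.134, adjusted p 0.0613), and 0.208 without replicate 1.

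Lists of regulators and cell-cycle genes did not pass either, and several passed or turned under alternatives. The Polycomb and Trithorax list had 13 of 29 bound (2.74, adjusted p 0.0523), with ph-p at 266 and Pc at 217. Replication and cell-cycle genes had 14 of 34 (2.36, adjusted p 0.0659), with CycB at 556 and Mcm5 at 213, and an odds ratio of 1.55 without replicate 2. The Hippo pathway had 9 of 21 (2.53, adjusted p 0.0994), with Diap1 at 216 and sav at 207, and 1.63 without replicate 1. Hox genes had 3 of 8 (2.02, adjusted p 0.464), with abd-A at 183 and lab at 81.5. Without replicate 1 the Hox odds ratio turned to 0.307, and without replicate 2 to 0.532. Heat shock and chaperone genes had 7 of 22 (1.57, adjusted p 0.413), with Hsp110 at 462 and DnaJ-1 at 311, and 2.58 without replicate 2. The Notch pathway had 6 of 24 (1.12, adjusted p 0.849), with mam at 226 and Su(H) at 191, and an odds ratio of 0.980 without replicate 2. With each peak given to its nearest TSS, the Polycomb (4.15, adjusted p 0.00167), Hippo (4.04, adjusted p 0.0112) and Hox lists (7.39, adjusted p 0.0303) passed. The Polycomb list also passed with a 1000 bp window (3.51), and with all protein-coding genes as background (3.39), as did the replication list then (2.78, adjusted p 0.0185). The highest adjusted p over alternatives was 1 for each. With the 500 strongest peaks, the odds ratios of the Polycomb, replication, Hippo, Hox and Notch lists fell below 1, to 0.345 at the lowest for Notch.

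Tissue and patterning lists did not pass the threshold. Mesoderm and muscle had 6 of 33 (0.747, adjusted p 0.750), with Mef2 at 171 and H15 at 169. Segmentation had 3 of 30 (0.373, adjusted p 0.202), with smo at 115 and odd at 105, and its odds ratio was 0.0853 without replicate 1 and 1.13 without replicate 2. Endoderm and gut had 2 of 18, lab and eIF4E1 with 93.7, a translation factor used in all tissues (0.420, adjusted p 0.464), and the odds ratio fell to 0.141 without replicate 1 and 0.1005 without replicate 2. Epidermis and trachea had 1 of 21, the E-cadherin gene shg with 203 (0.168, adjusted p 0.135), and 0.261 without replicate 1. The chorion and yolk list had 1 of 19 (0.186, adjusted p 0.169), with 0.290 without replicate 1 and 0.0953 without replicate 2. That member, Cp190 with 110, encodes an insulator protein that matched the list's symbol pattern by name alone. Of the 21 lists, 17 did not pass the threshold after adjustment, and 9 had an unadjusted p under 0.05.

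**Figure D2:**
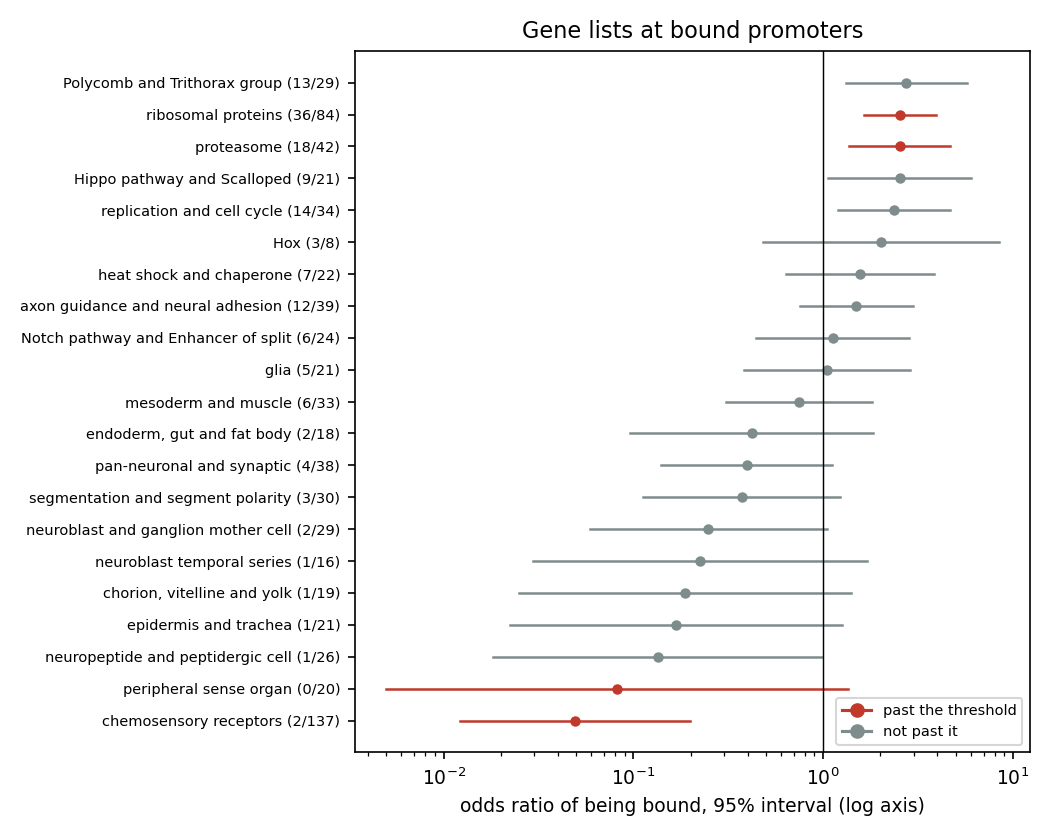
Odds ratio of being bound for members of each of the 21 gene lists against other genes (x axis, log scale), with 95% intervals as lines. Ribosomal protein genes at 2.54 and proteasome genes at 2.53 lie above 1 and chemosensory receptor genes at 0.0491 below it, and the interval of the peripheral sense organ list, with 0 bound members, reaches 1.35.

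Motifs were counted at summits to ask which sequences mark the bound sites. The DNA replication-related element (DRE), a promoter sequence read by DREF and BEAF-32, lay within 50 bp of 798 of 2793 summits (28.6%) and in 1.74% of flanking windows. Its odds ratio was 22.6 (18.2 to 28.1) with an adjusted p of 4.77e-299, against 1.45 for the reversed string. The share rose with signal, from 7.44% of the 699 weakest peaks through 22.8% and 38.3% to 45.8% of the 698 strongest, with 4 groups of nearly equal size. The weakest group held all 158 peaks with a signal under 30, of which 157 overlapped a stronger conservative peak. Location was not matched between the groups. The DRE share was 35.4% at promoters, 14.3% in 3′ UTRs (4 of 28), 16.7% in 5′ UTRs (1 of 6), 10.3% between genes, 2.65% in introns and 0 of 82 in coding exons. At summits outside promoters the odds ratio was 3.75 (2.16 to 6.54, adjusted p 3.79e-05), the highest adjusted p over the alternatives, and at the 500 strongest peaks it was 52.4. A DRE lay at 7 of the 15 named promoter peaks, those of Fit2, Capr, hts, kug, CkIIalpha-i1, EndoGI and CtsF, and at none of Ube3a, MESK2 and Rpn6. In the search of all 6-mers, 261 were more frequent and 422 less frequent at summits. The 6-mer TATCGA lay at 41.0% of summits and 4.28% of flanks, ATCGAT at 37.2% and 3.78%, and CGATAG at 33.1% and 2.95%. Of the 10 6-mers with the lowest p, 8 contained CGAT.

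**Figure D3:**
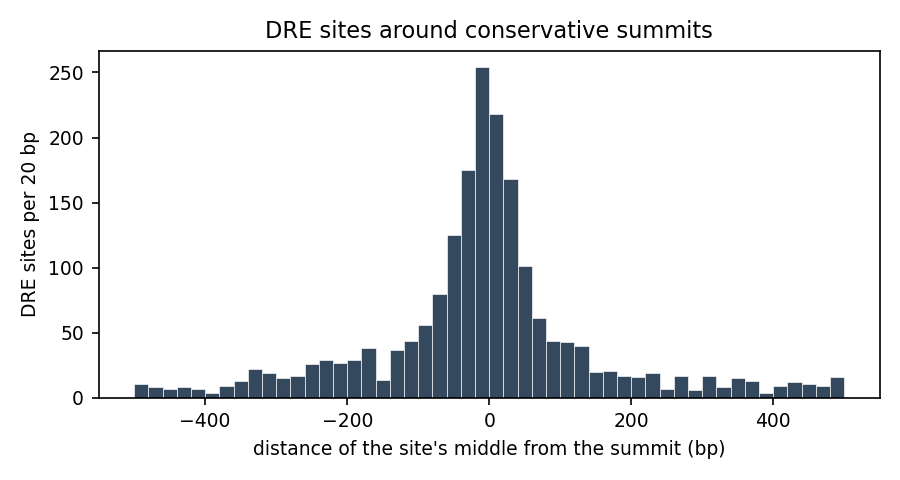
Number of DRE sites in bins of 20 bp (y axis) by distance from the conservative summit in bp (x axis). The 2 bins next to the summit held 254 and 218 sites, and the outermost bins 11 and 16.

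A further 4 motifs were more frequent at summits and 1 was less frequent. The core promoter sequence bound by M1BP lay at 2.86% of summits and 0.358% of flanks (odds ratio 8.21, 5.02 to 13.4, adjusted p 6.91e-21), and its reversed string had an odds ratio of 4.70. Against location-matched relaxed summits the M1BP odds ratio was 3.32. Outside promoters it did not pass the threshold (adjusted p 0.237, the highest in a range from 2.36e-32). The proneural E-box lay at 8.09% and 5.26% (1.58, adjusted p 4.65e-06). Without replicate 1 it had an odds ratio of 1.30 and an adjusted p of 0.0739, in a range of 2.52e-08 to 0.978. CTCF sites lay at 0.859% and 0.340% (2.54, adjusted p 0.0120), with 2.01 and 0.0644 without replicate 2, in a range of 0.000611 to 1. The reversed strings had odds ratios of 1.12 for the proneural E-box and 0.727 for CTCF. The Initiator lay at 9.63% and 7.91% (1.24, adjusted p 0.0292), close to the 1.22 of its reversed string. Its odds ratio was 1.01 without replicate 1 and 1.17 without replicate 2, neither past the threshold (adjusted p 0.0324 to 1 over alternatives), and 0.953 against matched relaxed summits. The Snail-family E-box was less frequent, at 3.54% and 5.10% (0.684, adjusted p 0.0064), and did not pass outside promoters or at the 500 strongest peaks. Its reversed string was depleted more, with 0.567, so the difference was not specific to the motif. The number of less frequent motifs rose to 2 without replicate 1 and 3 without replicate 2.

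The other 14 motifs did not pass the threshold. The core sequence bound by INSM1, the vertebrate relative, lay at 0.895% of summits and 1.11% of flanks (odds ratio 0.805, adjusted p 0.605), and its odds ratio was 1.07 without replicate 1 and 1.12 without replicate 2. Against location-matched relaxed summits it was 0.556 and passed (adjusted p 0.0289, range over alternatives 0.0289 to 1). The odds ratio was 0.929 for GAGA factor (adjusted p 0.839), which fell to 0.473 without replicate 1 and rose to 1.82 without replicate 2, there with an adjusted p of 0.00223, the lowest over alternatives that reached 1. It was 0.528 for GATA (adjusted p 0.0503), which passed with 0.283 without replicate 1 and 0.320 without replicate 2. It was 1.40 for core promoter motif 6 (adjusted p 0.107), which passed with 1.86 without replicate 1 and 1.94 without replicate 2, but turned to 0.604 outside promoters. The TATA box had 0.709 (adjusted p 0.0644) and Zelda 0.587 (0.286). For Runt it was 1.18 (0.286), for homeodomain sites 0.878 (0.393), for Ets 0.444 (0.548) and for Su(H) 1.13 (0.666). Su(Hw) had 0.666 (0.839), Scalloped 1.07 (0.839), Grainyhead 1.14 (1) and Mef2 1.00 (1). Without replicate 1 the odds ratio turned to 1.02 for homeodomain sites, 1.60 for Ets, 0.914 for Su(H) and 1.33 for Su(Hw). Without replicate 2 it turned to 0.827 for Scalloped, homeodomain sites passed with 0.736, and Su(Hw) had 0.222. Grainyhead rose to 2.00 without replicate 1 and 3.005 without replicate 2, and Zelda fell to 0.318 without replicate 1.

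The loci of nerfin-2 and nerfin-1 were examined because the tagged gene can bring extra copies of its own DNA. Around nerfin-2 (FBgn0041105, 3R 10071117 to 10073761, plus strand), 1 conservative peak lay within 10000 bp of the gene. It lay upstream at 3R 10070144 to 10070543, 773 bp from the TSS, with a signal of 67.0 and rank 2544 of 2796. The second list across replicates had 3 peaks within that distance. Replicate 1 had 2 thresholded peaks there, the stronger at 10076547 to 10076906, and replicate 2 had 1 at another site, 10061202 to 10061551. The wider region was dense in peaks. A window of 100 kb around nerfin-2 held 17 conservative peaks, against a median of 3 around 10000 random genes, 99.93% of which had fewer and none more than 18. The number of relaxed calls there was 130 against a median of 128. Without replicate 1 the window held 7 thresholded peaks, and without replicate 2 it held 11. The 17 peaks spanned 66.3 kb, from Mical and CG3909 to Fmr1, and 9 lay at promoters (52.9% against 77.2% elsewhere, odds ratio 0.333, Fisher's exact p 0.0363). Of the 17, 3 overlapped a stronger conservative peak, so they were not all separate sites. Around nerfin-1 (FBgn0028999, 3L 909112 to 912319), 0 thresholded peaks lay within 10000 bp in any of the 4 lists. Its 100 kb window held 3 conservative peaks, more than around 44.63% of random genes.

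**Figure D4:**
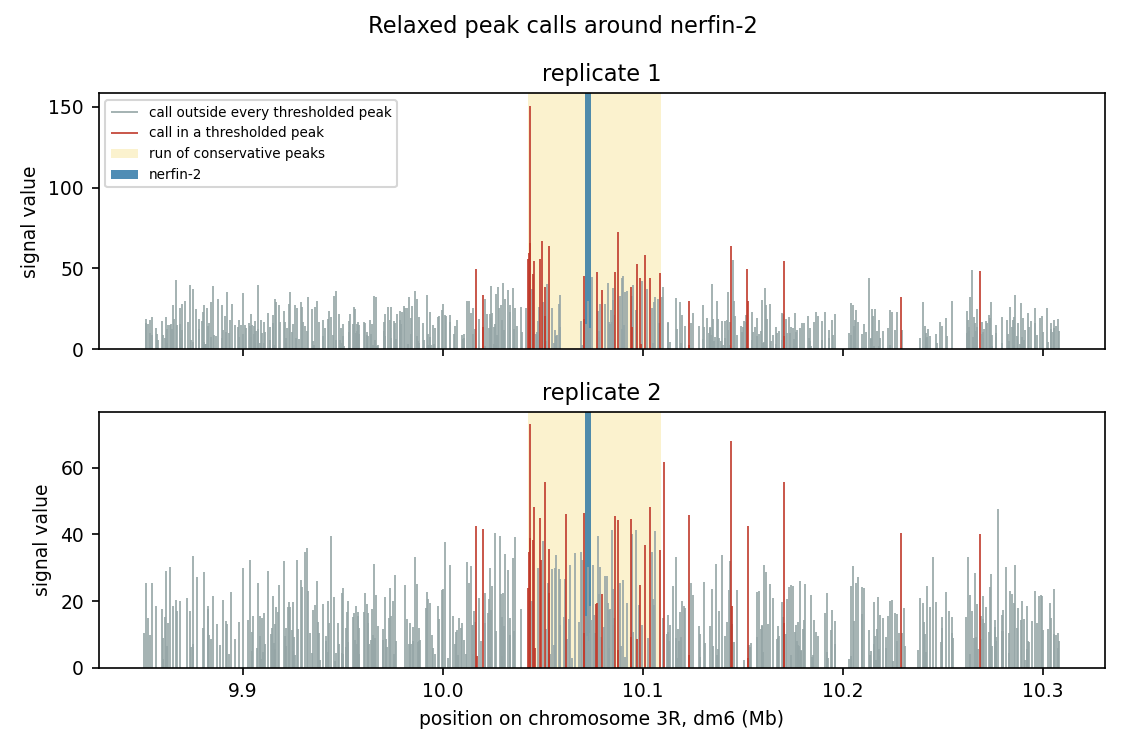
Signal of relaxed calls (y axis) by position on 3R (x axis) around nerfin-2 in each replicate, with calls in thresholded peaks in red, other calls in grey, nerfin-2 in blue and the stretch of 17 conservative peaks shaded. Outside thresholded peaks, the median signal in the shaded stretch was 24.2 in replicate 1 and 19.1 in replicate 2, against 15.5 and 13.8 in the sequence on each side.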

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

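Peaks outside the main chromosome arms entered no comparison, and their numbers were looked at only after the lists had been seen. Replicate 2 had 21 thresholded peaks on such contigs and the second list across replicates had 11, all on unplaced contigs assigned to X. They were singled out because both numbers are above 3, the most that a count of 0 allows, a limit for counting error only. The conservative list had 3 such peaks and replicate 1 had 1. The peaks of replicate 2 had a median signal of 57.1, and the relaxed lists held 724 calls on these contigs in replicate 2 and 408 in replicate 1. The sequence of these contigs was not analysed here, and no explanation, technical or biological, was tested.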

How the results depend on the processing

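Alternatives added after the data were seen were those without the peaks around nerfin-2, with the strongest of overlapping peaks, for the rank correlation, for the nerfin-2 window and the looser call for peaks of 1 replicate. With 2 replicates and no control analysed here, leaving out a replicate also changed how peaks were called, and depth is unknown from the lists. The promoter share lay between 71.4% and 90.4% under its 9 alternatives and stayed past its threshold. The overlap ran from 52.4% to 76.6% for replicate 1 and from 75.8% to 79.0% for replicate 2, with p 0.001, the smallest possible. The DRE odds ratio ran from 3.75 to 52.4, and the DRE, the 6-mer ATCGAT, the chemosensory list and the promoter shares of peaks of 1 replicate stayed past the threshold throughout. Of 96 main results under an alternative, 61 were the same and 35 moved. A count was called the same within a fixed factor of its main value, as 1900 bound genes were against 2709. An odds ratio or share was called the same when its direction and its passing of the threshold held, whatever its size. The rank correlation was called the same inside the interval of the main result. Of 489 values for single arms, lists and motifs, 366 were the same, 29 newly passed the threshold, 41 no longer passed it and 53 changed side of 1. Of those 53, 46 passed the threshold neither before nor after, 5 passed it before (arm 3R, chromosome 4 and the Initiator) and 2 after (GAGA factor). Logistic regression gave no estimate for the peripheral sense organ list, which had no bound member, so its adjustment ran over 20 lists. Why values changed was not tested for any alternative, including those with fewer peaks.

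The rank correlation was 0.778 over all conservative peaks and 0.661 over the 500 strongest pairs. With all protein-coding genes as background, 4 lists were bound more often. Logistic regression gave odds ratios of 0.982 for axon guidance and 0.816 for glia. With the nearest TSS, 4 lists were bound more and 1 less often, and the odds ratio was 1.11 for gut and 1.02 for the temporal series. With a 1000 bp promoter window, glia had 0.859. With 250 bp, glia had 0.716 and 4 lists were bound less often.

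Outside promoters, 2 motifs were more and 3 less frequent, with odds ratios of 1.34 for GAGA factor, 1.05 for the INSM1 core, 4.01 for Su(Hw) and 0.604 for motif 6. At promoters, they were 0.976 for Scalloped, 0.961 for Su(H) and 1.04 for homeodomain sites. Against matched relaxed summits, 3 motifs were less frequent, with 0.796 for Grainyhead, 0.953 for the Initiator, 0.995 for Scalloped and 1.25 for homeodomain sites. With windows of 100 bp, 2 motifs were less frequent, with 1.16 for GAGA factor and 1.16 for homeodomain sites.

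With the strongest of overlapping peaks, 2 motifs were less frequent, 1 list was bound more and 1 less often, and odds ratios were 1.01 for X, 0.892 for Notch and 0.857 for Grainyhead. Without the peaks around nerfin-2, 1 list was bound less often. With the second list, 3 arms passed, 4 motifs were less frequent, 1 list was bound more and 1 less often, and odds ratios were 0.926 for glia, 1.57 for GAGA factor and 0.907 for Scalloped.

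With the 500 strongest peaks, 659 genes were bound, 117 6-mers were more and 175 less frequent, 1 arm passed, 2 motifs were more and 0 less frequent, 0 lists were bound more and 1 less often, and the nerfin-2 window held 0 peaks. Odds ratios were 1.03 for 3R, 0.983 for chromosome 4, 1.09 for X, 0.393 for Hippo, 0.995 for Hox, 0.345 for Notch, 0.604 for Polycomb, 0.445 for axon guidance, 0.846 for glia, 0.512 for replication, 0.872 for the Initiator and 0.696 for Scalloped.

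Leaving out a replicate gave 2 to 4 arms, 2 to 3 less frequent motifs, 1 to 1 lists bound less often, 1 to 2 bound more often and 7 to 11 peaks around nerfin-2. Odds ratios ran from 0.990 to 2.35 for chromosome 4, 0.983 to 1.14 for X, 0.307 to 0.532 for Hox, 0.549 to 0.876 for glia, 0.980 to 1.04 for Notch and 0.0853 to 1.13 for segmentation. For motifs they ran from 0.363 to 1.60 for Ets, 1.07 to 1.12 for the INSM1 core, 0.914 to 1.11 for Su(H), 0.222 to 1.33 for Su(Hw), 0.736 to 1.02 for homeodomain sites, 0.473 to 1.82 for GAGA factor and 0.827 to 1.03 for Scalloped.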

Other observations

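Chosen only after their results were seen were the counts by gene type, the tests on ribosomal protein genes with and without a DRE, on high transcription of tRNA genes, on isolated tRNA genes, on weak peaks and on DREs at peaks matched to those around nerfin-2, the counts over sliding windows and the 6-mers at summits without a DRE. Transfer RNA genes were bound more often than any other gene type counted. A conservative summit lay within 500 bp of the 5′ end of 172 of 290 tRNA genes (59.3%, 53.6 to 64.8). Many lie in clusters that share a summit, and of those over 1000 bp from every other tRNA gene 40 of 107 were bound (37.4%, 28.8 to 46.8). The same count gave 18.4% of protein-coding genes, 4 of 32 small nuclear RNA genes (12.5%), 17 of 269 small nucleolar RNA genes (6.32%) and 0 of 99 ribosomal RNA genes. The strongest peak at tRNA genes lay in a group on 2R with tRNA:Gly-GCC-1-12 (21161356 to 21161426), with a signal of 372, followed by tRNA:Gly-TCC-1-2 on 3R with 350, both named after their values were seen. Of the 642 summits away from protein-coding promoters, 108 (16.8%) lay within 500 bp of a tRNA gene. Summits near tRNA genes, 4.40% of all, lay a median of 53 bp from the gene's 5′ end, and 0% of them had a DRE. The share was 57.6% in replicate 1 and 44.8% in replicate 2.

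Beyond the fixed lists, 23 gene families were written down after the lists had been opened but before any family was tested. Among 12 families used by most cells, 6 were bound more often, namely vacuolar protein sorting (13 of 21, odds ratio 5.48, adjusted p 0.00111), Sm and LSm proteins (6 of 10, 5.05, adjusted p 0.0294), Rab GTPases (15 of 29, 3.62, adjusted p 0.00388), nucleoporins (11 of 23, 3.09, adjusted p 0.0256), translation initiation factors (18 of 40, 2.76, adjusted p 0.00779) and mitochondrial ribosomal proteins (28 of 72, 2.15, adjusted p 0.00898). Examples, chosen after their values were seen, were mRpL30 with a signal of 497, eIF3f1 with 492, Nup75 with 481, Vps29 with 460, Rab30 with 422 and SmB with 363. Among 11 tissue-restricted families, 5 were bound less often, namely cuticular proteins (0 of 96, adjusted p 4.42e-10), odorant-binding proteins (0 of 38, adjusted p 0.00111), cytochrome P450 (5 of 66, adjusted p 0.00779), Osiris (0 of 20, adjusted p 0.0210) and glutathione S-transferases (1 of 26, adjusted p 0.0366). Odds ratios were above 1 in all 12 of the first kind and below 1 in all 11 of the second, and 39.3% and 3.62% of members were bound. In the first kind, RNA polymerase II subunits (1.01, 0.277 to 3.67) and respiratory complex I (1.08, 0.509 to 2.29) lay close to 1. The test asked for more than 50% of families of each kind past the threshold, which neither reached. A small family could miss the threshold with no member bound, as Jonah and trypsin proteases did with 0 of 14 (Fisher's exact test, adjusted p 0.0827). Size alone did not decide, since the smallest family, Sm and LSm proteins, passed. Some larger families missed the threshold with shares near that of other genes, such as aminoacyl-tRNA synthetases (8 of 30, 26.7% against 22.9%). All odds ratios of a kind lay on the same side of 1, some of them barely. Whether wide use goes with binding in each family by itself stayed open.

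The DRE at summits was set against 3 explanations. Nearness to protein-coding promoters alone was argued against for summits farther than 500 bp from every protein-coding TSS, where the odds ratio was 3.75 (2.16 to 6.54). Such summits can still lie at starts of non-coding genes. Peaks 20 bp from asRNA:CR45009 and 118 bp from snRNA:7SKa did, though neither had a DRE. Nearness to such starts was not tested. Against relaxed summits matched on location class the DRE odds ratio was 22.3 (17.8 to 28.0). That match did not cover distance to the TSS, and 56.0% of conservative and 3.35% of relaxed summits lay within 100 bp of one. The value of 22.3 therefore cannot separate the DRE from nearness to the TSS. Whether summits simply mark the TSS, with the DRE near it by its place in the promoter, cannot be told apart from binding at the DRE: the DRE was closer to the summit than to the TSS in 53.7% (50.9 to 56.5) of 1208 promoter peaks, and the distances were too alike to decide. For signal at heavily transcribed genes whatever their sequence, a test on all tRNA genes written down after the lists had been opened but before its result was seen, whose summits had no DRE, went with the explanation (59.3% bound against 52.8% of protein-coding genes with a DRE, odds ratio 1.30, Fisher's exact p 0.0358), but it counts clustered genes as independent and turned for isolated ones (37.4%, odds ratio 0.533, p 0.00211). Among ribosomal protein genes 27 of 35 with a DRE and 9 of 49 without were bound (odds ratio 15, 5.14 to 43.7, Fisher's exact p 1.04e-07). This would argue against transcription as the whole cause only if the listed genes are transcribed alike, which was assumed and not measured. The symbol pattern also took in related copies such as RpS5b and RpS19b, so the test cannot separate the DRE from transcription. Binding through DREF, BEAF-32 or the promoter's open chromatin, with or without the tagged protein, may lie behind the pattern, and with no control library analysed here no biological explanation was tested.

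The binding of tRNA genes was set against 3 explanations. Nearness to bound protein-coding promoters was argued against, because 91 of 167 tRNA genes farther than 2000 bp from every protein-coding TSS (54.5%, 46.9 to 61.9) were bound, as were 20 of 62 (32.3%, 22.0 to 44.6) of those also isolated from other tRNA genes. High transcription alone cannot be told apart from binding, because ribosomal protein genes without a DRE were bound 0.310 times as often as all tRNA genes but 0.491 times as often as isolated ones (Fisher's exact p 0.0250) and 0.531 times as often as those with a sequence of their own (p 0.0755), around the bound of 0.5 that was set. Reads shared between identical copies cannot be told apart from binding, because the share bound was 34.6% (18 of 52) for tRNA genes with a sequence of their own and 64.7% (154 of 238) for those with a copy, a ratio of 0.535 that lay between the bounds set for either outcome. No control library was analysed here, so immunoprecipitation of tRNA genes without the tagged protein may contribute, and no biological explanation was tested.

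The dense peaks around nerfin-2 were set against 2 explanations. Extra copies of the tagged locus may add signal over the whole region, and outside thresholded peaks the median signal was 1.56 (1.04 to 1.89) times that of the 200 kb on each side in replicate 1 and 1.38 (1.08 to 1.87) times in replicate 2. No other window of arm 3R reached the region's median, of 442 in replicate 1 and 477 in replicate 2, but the stretch with the sharpest contrast differed between replicates (10078678 to 10110190 and 10012112 to 10106184). Binding sites of the kind found elsewhere would carry DREs as often, and 1 of the 17 peaks did (5.88% against 28.7% of all others, Fisher's exact p 0.0545), but 10 of the 17 were among the weakest peaks, and others of like signal and promoter class would give 2.32 (one-sided p of as few 0.276), so 17 peaks are too few to decide. The planned rule would have taken that p as going with this explanation and was tightened after the value was seen, so neither explanation can be told apart from the other while the copy number is unknown and replicate 2 falls short of the ratio of 1.5 set for extra copies.

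With the DRE as a covariate, the odds ratio of the ribosomal list was 1.92 (1.17 to 3.16, p 0.0101) and that of the proteasome list 1.64 (0.812 to 3.31, p 0.168), so an excess of the ribosomal list was left with the covariate. Among genes with a DRE, 27 of 35 ribosomal protein genes (77.1%) and 56.4% of the others were bound (odds ratio 2.60, 1.18 to 5.75, p 0.0155). Among genes without a DRE the numbers were 9 of 49 (18.4%) and 13.1% (odds ratio 1.49, 0.721 to 3.08, p 0.287). How far the DRE accounts for the list stayed open. Of 158 conservative peaks with a signal under 30, 157 (99.4%) overlapped a stronger conservative peak, against 2.69% of the others. At 1995 summits without a DRE, CGATAG lay at 18.9% against 2.86% of flanks and ACTATC at 15.3% against 3.53%. TATCGA lay at 18.6% against 4.34% and ATCGAT at 12.1% against 3.83%. Both are part of the DRE consensus WATCGATW, so summits counted as without a DRE can still hold partial matches to it. The 100 kb window with the most peaks was the one on 3R that holds nerfin-2, with 18, followed by windows on 2R with 15, of which the one at 6142192 to 6242191 had 6.67% of its peaks at promoters.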
